A study of Homo sapiens with 43 samples.

How the data were processed

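CUT&RUN libraries of 4 human neuroblastoma cell lines were compared through the peak lists deposited for them. Of 43 samples, 38 have a list used here: 20 BPTF, 8 GATA3, 8 YAP1 and 2 histone mark libraries. The other 5 are MNase samples, 1 for each line or condition, and were not analysed here. The authors called the peaks with MACS2 on build hg19 and name HOMER for annotation. Their versions, the aligner, the read filters and the control library behind each list are not given in the sources used here. Narrow lists hold peaks with an unadjusted p of at most 0.05 and the broad H3K27me3 list holds peaks with p of at most 0.1, as the values show.

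In each deposited list the authors give per peak a fold enrichment (ratio over the local background), the −log10 of p and of q, a score of 10 times the −log10 p and, in narrow lists, the summit offset in bases. These are each peak's own values, and they serve here only to rank, filter or describe peaks within a list. Read counts and library depths are not in the lists, so the depth is unknown and no counting interval is given. The number of peaks in a list is not a depth. Lists of the 36 BPTF, GATA3 and YAP1 libraries hold 184092 to 536349 peaks, and 6 to 34370 of them have q of at most 0.01.

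So that every list has the same length, the main comparisons take the 20000 peaks with the highest −log10 p on chromosomes 1 to 22 and X from each library, called top peaks below. Their weakest member has a −log10 p of 3.24 to 6.96, depending on the library. Identical intervals were kept once, and ties were broken by fold enrichment and then position. Intervals overlap when they share at least 1 bp. For a comparison, the top peaks of both groups were merged into regions, and a region separates the groups when every library of a group and no library of the other has a top peak there. The total was set against the other splits of the same libraries into groups of these sizes, all of them or 100 drawn with a fixed seed. No single region was called, because a test per region cannot pass a Benjamini-Hochberg adjustment at these group sizes. A recurring region has a top peak in at least 3 libraries of its group.

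Overlap with a map was measured as the percent of a library's top peaks that overlap it, and as the log2 ratio of that number to the mean over 20 circular shifts of the peaks along their chromosomes, with 0.5 added to both. In KELLY the map was every deposited H3K4me3 or H3K27me3 peak. For the description of all groups it was the 20000 strongest peaks of each mark list. Library similarity is the Jaccard index, shared bases over covered bases, of the top peaks of a pair of libraries. Group differences were tested with exact two-sided permutation tests, the marks in KELLY with an exact two-sided sign-flip test, and similarity with an exact one-sided permutation of the group labels. For differences between antibodies, the mean effect of both antibodies was first subtracted from the induced values. Condition labels were then permuted within each antibody, which makes this test approximate. BPTF libraries are recorded with 10 µg of antibody, GATA3 and YAP1 libraries with 1 µg and the marks with 0.5 µg. Differences between BPTF and the other antibodies therefore cannot be told apart from the amount used. Benjamini-Hochberg adjusted values are given with the number of tests in their family. Regions are named by a fixed rule: the 5 in each direction with the best median rank within their libraries. Groups were taken from the sample labels. Replicate numbers were not treated as pairs in the main tests, and a blocked test was run as an alternative. No value was compared by a test between KP-N-YN and the other lines, which were processed at different centres.

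These choices were made before the data were examined. Chosen afterwards were the comparison of all groups with the mark maps, the tests between antibodies, the regions shared by all KELLY, LAN-1 and SK-N-AS BPTF libraries, the share of BPTF regions of induced cells at GATA3 regions with a library left out, and the peak density. For the density, all deposited peaks were counted in windows of 1 Mb on the 22 autosomes. Windows with a median over libraries above 10 peaks were kept, which left 2703, and each count plus 1 was divided by its library's median window on the log2 scale. Correlations of densities run across windows, which are not independent replicates. The alternatives also chosen afterwards left out the interval from 15 to 17 Mb of chromosome 2, chromosomes 1, 2 and 10, pairs of libraries that stand apart, libraries beyond 3 in KELLY and LAN-1, or mark peaks with q above 0.01. Alternatives chosen before were the top 50000 peaks, all deposited peaks, peaks with q of at most 0.01, a difference of at least 0.75 in the share of libraries, the summit in place of the interval, the replicate block and each library left out in turn. With no hg19 gene annotation at hand, no peak was assigned to a gene, and the planned gene lists, locus scores and motif searches were not run. Coordinates are hg19 and 1-based.

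The separation count was tested on simulated data drawn from the real regions of each of the 6 comparisons. When 200 regions had a peak with a chance of 0.9 in each library of a group and 0.1 in the other, 40.2% to 48.1% were counted on average over 20 draws, against 38.7% to 47.8% expected, so the count misses regions that a single library lacks. With no group effect and each region's libraries shuffled, 20 draws gave 64 to 110 regions for KELLY against SK-N-AS, 150 to 180 for LAN-1 against SK-N-AS, 17 to 28 for KELLY against LAN-1, 31 to 58 for KP-N-YN BPTF, 87 to 126 for GATA3 and 1 to 7 for YAP1. Drawing each library anew at each region's share gave 139, 326, 34, 107, 130 and 62, and up to 201, 333, 50, 110, 148 and 87 in other splits. A random map gave a log2 overlap of 0.03. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.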

Results

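CUT&RUN maps the genomic positions of a protein by letting an antibody direct a nuclease to cut the DNA around it. The series holds 20 libraries for BPTF, the largest subunit of the NURF chromatin remodelling complex. They come from KELLY (5 libraries) and LAN-1 (4), neuroblastoma lines with amplified MYCN, from SK-N-AS (3), a line without the amplification, and from KP-N-YN cells (8). The KP-N-YN cells carry a doxycycline-inducible PRRX1, a factor used to move neuroblastoma cells from an adrenergic to a mesenchymal state, and were profiled under control conditions and after induction with 4 libraries each for BPTF, for the adrenergic factor GATA3 and for the Hippo pathway effector YAP1. KELLY also has 1 library each for H3K4me3, a mark of active promoters, and H3K27me3, a mark of Polycomb-repressed chromatin. Nothing in the labels says whether replicates are separate cultures, so p-values measure spread between libraries that may be technical.

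In KELLY, BPTF lay at H3K4me3, while its overlap with H3K27me3 was close to that of shifted peaks and changed sign with the length of the BPTF list. Of the top BPTF peaks, 39.7% ± 6.7 (SD, n = 5) overlapped a deposited H3K4me3 peak, against 5.56% for the same peaks shifted along their chromosomes, a log2 ratio of 2.82 ± 0.22. For H3K27me3 the overlap was 24.8% ± 1.4 against 23.2%, a log2 ratio of 0.09 ± 0.10. H3K4me3 exceeded H3K27me3 by 2.72 ± 0.31 on the log2 scale and did so in 5 of 5 libraries (exact two-sided sign-flip p 0.0625, the smallest that 5 libraries allow). The H3K27me3 map was so wide that even full overlap would keep its ratio below the 2.82 of H3K4me3. Map width therefore fixed the sign of this difference, and the test does not compare the marks. The H3K27me3 ratio was 0.19 ± 0.09 with the top 50000 peaks and 0.32 ± 0.03 with all deposited peaks, above 0 in every library, and -0.33 ± 0.05 with the stricter peaks of q at most 0.01 in each BPTF list (n = 5 each). Mark peaks with q of at most 0.01 made narrower maps, met by 1.88% of shifted peaks for H3K4me3 and 2.82% for H3K27me3. On these the ratios were 4.04 ± 0.28 for H3K4me3 and 0.06 ± 0.60 for H3K27me3 (n = 5 each).

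The same location was found in the other lines, measured on the 20000 strongest KELLY mark peaks. Top BPTF peaks overlapped this H3K4me3 map in 30.9% ± 6.4 of cases in KELLY (n = 5), 24.1% ± 9.4 in LAN-1 (n = 4), 42.2% ± 4.8 in SK-N-AS (n = 3) and 33.1% ± 11.4 in KP-N-YN control cells (n = 4). BPTF in PRRX1-induced cells reached 5.15% ± 3.10 (n = 4). GATA3 overlapped it in 12.5% ± 3.7 of top peaks in control and 5.37% ± 3.30 in induced cells, and YAP1 in 6.19% ± 1.60 and 3.25% ± 1.40 (n = 4 each). The lines' mark profiles other than KELLY's were not analysed here.

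**Figure D1:**
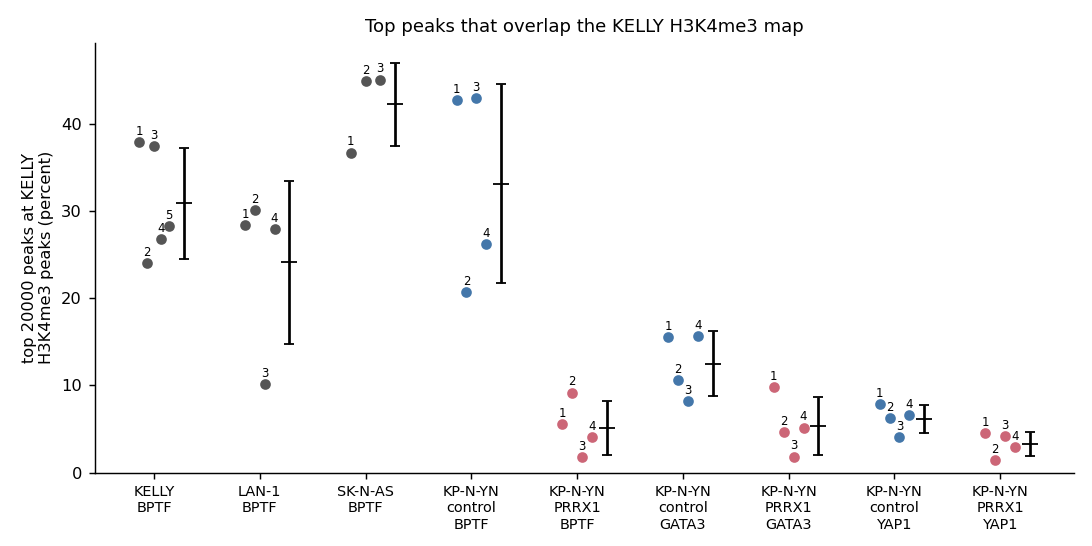
Percent of each library's 20000 top peaks that overlap the 20000 strongest H3K4me3 peaks of KELLY, by group; points are libraries with their replicate number, bars are mean and SD. The BPTF libraries of PRRX1-induced cells lie between 1.79% and 9.17%, below the 20.7% to 42.9% of the control BPTF libraries.

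A core of BPTF regions was shared by KELLY, LAN-1 and SK-N-AS, and most of it was found in KP-N-YN control cells as well. There were 667 regions with a top peak in all 12 BPTF libraries of KELLY, LAN-1 and SK-N-AS. Of these, 96.7% overlapped the H3K4me3 map, and 74.2% overlapped a recurring BPTF region of KP-N-YN control cells. They were densest on chromosome 6 between 26 and 27 Mb, with 12 regions, in band 6p22 that holds the main histone gene cluster. In single KP-N-YN control BPTF libraries, 77.1% ± 17.2 (n = 4, from 59.4% to 97.9%) of the 667 regions held a top peak.

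SK-N-AS held many more BPTF regions of its own than either MYCN-amplified line. Against KELLY, 1626 regions had a top peak in all 3 SK-N-AS libraries and in none of the 5 KELLY libraries, while 102 regions went the other way. Against LAN-1 the numbers were 2021 and 30. Among the 1626 regions 40.9% overlapped the KELLY H3K4me3 map, against 75.5% of the 102 KELLY regions and 96.9% of the 1579 regions present in all 8 libraries. A map from KELLY favours KELLY regions and can lack promoters marked only in SK-N-AS. The contrast therefore does not show that SK-N-AS regions lay less often at promoters. The real grouping separated more regions than any of the other splits of the same libraries, 1728 against at most 257 over 56 splits for KELLY, and 2051 against at most 584 over 35 splits for LAN-1. A region counts as a group's own only when each of its libraries has it, which 3 libraries meet more easily than 4 or 5. In all SK-N-AS libraries there were 6961 regions and in all KELLY libraries 1909. Group size gave only part of this gap: 3 KELLY libraries shared 2111 to 3558 regions and 3 LAN-1 libraries 1233 to 2534. With 3 libraries on each side, each of the 10 choices of KELLY libraries gave 135 to 358 regions only in KELLY and 1867 to 2382 only in SK-N-AS, and each of the 4 choices of LAN-1 libraries 43 to 125 only in LAN-1 and 2089 to 2553 only in SK-N-AS. Presence of a peak also depends on how strong a library is. SK-N-AS lists held 14625 ± 6919 peaks with q of at most 0.01 (n = 3), KELLY lists 5400 ± 2352 (n = 5) and LAN-1 lists 3568 ± 2017 (n = 4). SK-N-AS libraries were also the most alike of these lines, with a mean Jaccard index of 0.313 against 0.135 within KELLY and 0.0868 within LAN-1. With all deposited peaks, other splits separated up to 15146 regions, more than the real 6332 of KELLY against SK-N-AS (2472 only in KELLY, 3860 only in SK-N-AS), and up to 8839, more than the real 7619 of LAN-1 against SK-N-AS (1676 and 5943). Without SK-N-AS replicate 1 the totals rose to 3522 against KELLY and 4063 against LAN-1, and without replicate 2 to 2602 and 2948. Without LAN-1 replicate 4, described below, 87 regions were only in LAN-1 and 2553 only in SK-N-AS. The SK-N-AS libraries were uneven on chromosome 2 from 15 to 17 Mb, around MYCN, where replicates 1 and 3 had 430 and 319 top peaks and replicate 2 had 3, although the line lacks the amplification. Without this interval the total against KELLY was 1727. The rule nearly fixed this value, since an SK-N-AS region needs a top peak in replicate 2 as well.

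Among the SK-N-AS regions absent from KELLY, the strongest lay on chromosome 6 from 32811435 to 32812793, with a median rank of 273 in its libraries and an authors' fold enrichment of 8.07 to 18.5, and the fourth lay close by from 32805913 to 32807146. Both fall in band 6p21, the location of the MHC, and the first was also the strongest SK-N-AS region absent from LAN-1. The others were on chromosome 19 from 18132521 to 18133516, chromosome 12 from 50360588 to 50361821 and chromosome 1 from 172819957 to 172820762. The strongest KELLY region absent from SK-N-AS was on chromosome 7 from 807005 to 808399, with a median rank of 15 and an H3K4me3 peak in KELLY. The same place, as chromosome 7 from 806948 to 808510, ranked at a median of 5 in LAN-1 and was also absent from all SK-N-AS libraries. The strongest LAN-1 region absent from SK-N-AS was on chromosome 21 from 45936521 to 45937725, at a median rank of 4.

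KELLY and LAN-1 differed in few regions, 71 only in KELLY and 11 only in LAN-1. Of the 71, 91.5% overlapped the KELLY H3K4me3 map. The strongest KELLY region was on chromosome 8 from 67038890 to 67039706 (median rank 867) and the strongest LAN-1 region on chromosome 12 from 57480724 to 57482776 (median rank 1900). Of 100 splits, 4 separated as many regions as the real 82, and the highest separated 158. LAN-1 replicate 4 stood apart from the other LAN-1 libraries in peak density along the genome. Its departure from the mean profile of the 12 libraries correlated across 1-Mb windows at r = 0.22 to 0.70 with the KELLY libraries and at -0.66 to -0.62 with LAN-1 replicates 1 to 3, which correlated with each other at 0.74 to 0.88. The KELLY libraries were uneven among themselves, at -0.011 to 0.89. Taking departures from a shared mean lowers r between groups. On the log2 density itself, LAN-1 replicate 4 correlated at 0.67 to 0.86 with the KELLY libraries and at 0.14 to 0.21 with LAN-1 replicates 1 to 3, which correlated with each other at 0.90 to 0.94. Without it, 232 regions were only in KELLY and 83 only in LAN-1, a total of 315 against at most 268 in the other 55 of 56 splits. Without LAN-1 replicate 3, which had the weakest H3K4me3 overlap of its group, the direction turned, with 73 regions only in KELLY and 87 only in LAN-1. All deposited peaks gave 1651 and 688, and a difference of at least 0.75 in the share of libraries gave 520 and 217.

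**Figure D2:**
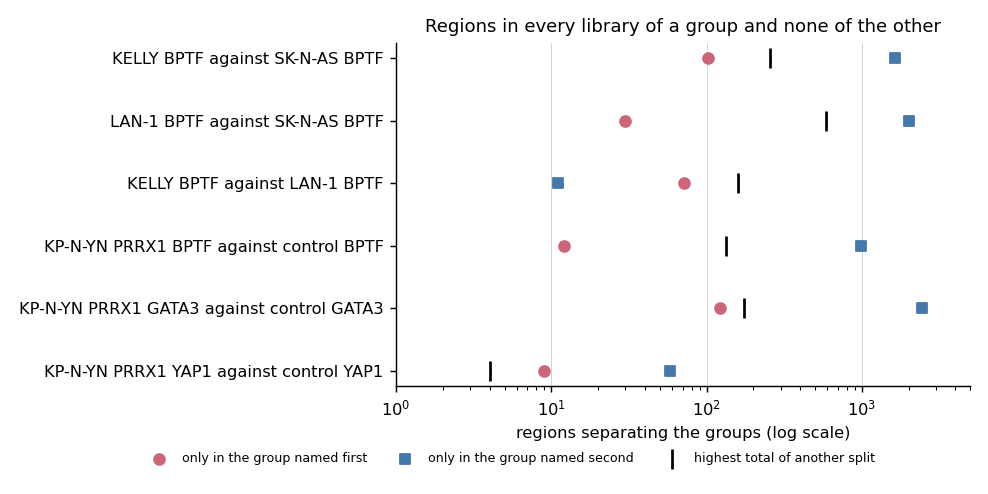
Number of regions with a top peak in every library of a group and in none of the other, on a log axis; circles count regions of the group named first, squares those of the group named second, and bars mark the highest total of another split of the same libraries. KELLY against LAN-1 is the comparison in which another split (158) exceeded the real total (82).

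**Figure D3:**
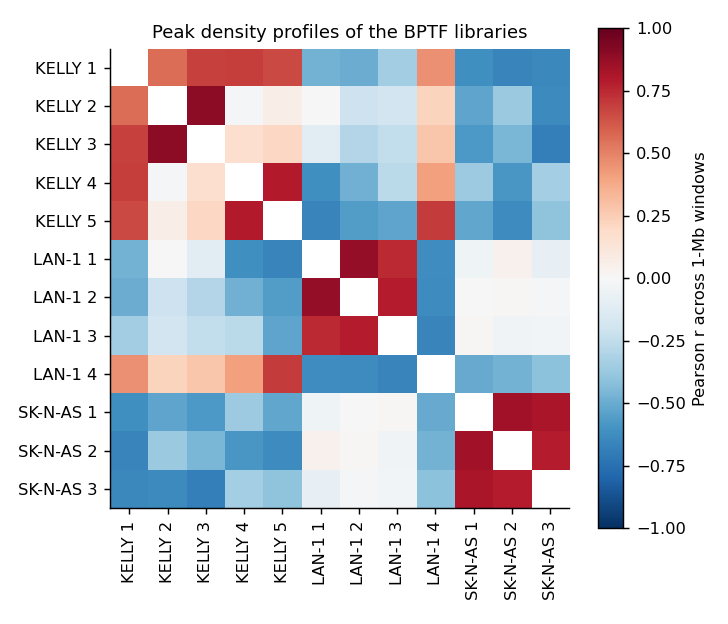
Pearson r across 2703 windows of 1 Mb between the peak density profiles of the 12 BPTF libraries of KELLY, LAN-1 and SK-N-AS, each taken as its departure from their mean. LAN-1 replicate 4 correlates with the 5 KELLY libraries (0.22 to 0.70) and not with LAN-1 replicates 1 to 3 (-0.66 to -0.62).

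Averaged over all pairs, libraries of the same line were more alike than libraries of different lines, with a mean Jaccard index of 0.148 within and 0.116 between lines, a difference of 0.0321 (exact one-sided permutation p 0.0206 over 27720 labelings). This rested on SK-N-AS, with 0.313 within the line. The 0.0868 within LAN-1 was below the 0.0967 of LAN-1 with KELLY and the 0.119 of LAN-1 with SK-N-AS, and the 0.135 within KELLY was below the 0.139 of KELLY with SK-N-AS. Leaving out any of the 3 SK-N-AS libraries gave differences of 0.0148 to 0.0168 that no longer passed 0.05.

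Induction of PRRX1 in KP-N-YN addresses what happens to BPTF, GATA3 and YAP1 when cells are moved towards the mesenchymal state. Far fewer BPTF regions recurred after induction. Control cells had 4809 recurring BPTF regions and induced cells 229, and 989 regions had a top peak in all 4 control and no induced library, against 12 the other way. Of the 989 regions, 83.4% overlapped the H3K4me3 map and 24.5% overlapped a recurring GATA3 region of control cells. The total of 1001 exceeded the other splits of the 8 libraries, of which the highest gave 134 (35 splits). With all deposited peaks, 5209 regions were only in control and 720 only in induced libraries, and with peaks of q at most 0.01 the numbers fell to 155 and 1. Without control replicate 2 or 4 the total rose to 2166 and 2069. With any of the 4 induced libraries left out, 1 or 2 other splits separated more regions than the real one (1118 against 1237 without replicate 1, 1182 against 1299 without replicate 2, 1056 against 1181 without replicate 3 and 1095 against 1203 without replicate 4). Induced libraries shared 2.42% of their top peaks with each other on average, against 21.7% among control libraries, so few regions can recur in them for any reason. The overlap of BPTF with the H3K4me3 map fell by 2.63 on the log2 scale (exact two-sided permutation p 0.0286, the smallest for 4 against 4, and 0.103 adjusted over 18 tests). Induced lists held only 6 to 173 peaks with q of at most 0.01, so most of their top peaks were weak. Of the 100 strongest peaks, 47%, 75%, 3% and 16% lay at the map in induced replicates 1 to 4, against 77% to 94% in control libraries. The fall at the strongest peaks was thus uneven between induced libraries.

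The 667 regions shared by the other lines give the same direction on a set defined without KP-N-YN. BPTF top peaks were present at 77.1% ± 17.2 of them in control libraries and at 21.9% ± 18 in induced libraries (n = 4 each, exact two-sided permutation p 0.0286, adjusted over 3 tests 0.0857), with every induced library (1.65% to 40.9%) below every control library (59.4% to 97.9%). GATA3 peaks were at 16.8% ± 9.3 and 11.8% ± 10.7 of them (exact p 0.457), and YAP1 peaks at 5.55% ± 3.02 and 9.07% ± 7.98 (exact p 0.429). The change in H3K4me3 overlap differed between BPTF and YAP1 by -1.66 on the log2 scale (permutation p 0.0245, adjusted over 6 tests 0.0490), and between BPTF and GATA3 by -1.27 (p 0.0894, adjusted 0.134). Induced BPTF libraries also had fewer peaks with q of at most 0.01, 101 ± 78 against 4297 ± 4267 (n = 4 each, exact two-sided permutation p 0.0286, adjusted over 6 tests 0.0714).

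**Figure D4:**
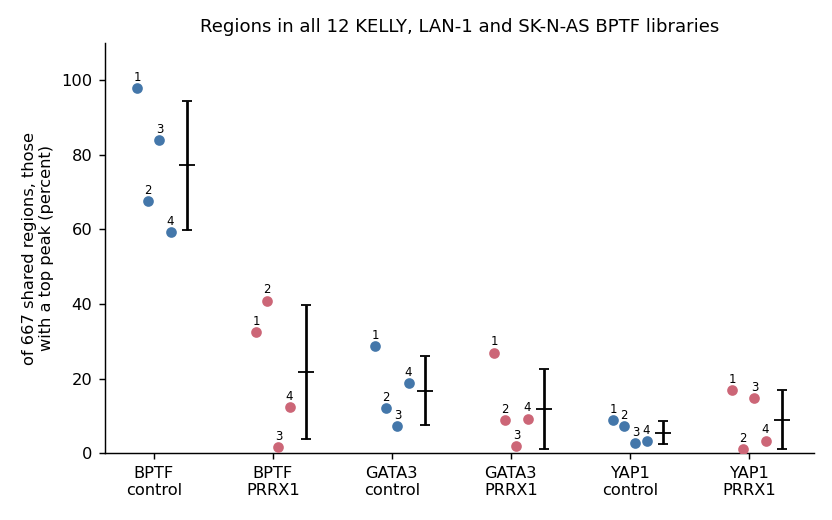
Percent of the 667 regions shared by the 12 BPTF libraries of KELLY, LAN-1 and SK-N-AS that hold a top peak in each KP-N-YN library; points are libraries with their replicate number, bars are mean and SD (n = 4). Control BPTF libraries lie between 59.4% and 97.9% and induced BPTF libraries between 1.65% and 40.9%.

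The recurring GATA3 regions of induced cells were largely different from those of control cells, and fewer. Control cells had 7243 recurring GATA3 regions and induced cells 2493, of which 281 (11.3%) overlapped a control region. All control and no induced libraries shared 2434 regions, and 122 went the other way, a total of 2556 against at most 173 in other splits (35 splits). Induced GATA3 libraries were less alike than control libraries, sharing 11.2% of top peaks with each other (1.99% to 24.9%) against 32.2% (21.9% to 47.1%), and 5.00% between conditions. Of the 4, replicates 2 to 4 had 43 to 1981 peaks with q of at most 0.01, and weak or uneven lists can by themselves lower the number of recurring regions and their overlap. For the overlap, the strongest peaks argue against weak lists alone in replicates 1, 2 and 4, which had 34370, 1981 and 1141 such peaks. Of their 500 strongest peaks, 15.6% to 16% lay at recurring control regions, against 99% to 99.8% in control libraries, which define these regions. Replicate 3, with 43 such peaks, had 0.8%. Without induced replicate 3, 2472 regions were only in control and 1602 only in induced libraries, and without control replicate 3 the numbers were 4073 and 125. All deposited peaks gave 4400 and 2615, peaks with q of at most 0.01 gave 804 and 7, and a difference of at least 0.75 in the share of libraries gave 6029 and 1791. The 122 regions gained after induction lay away from promoters marked in KELLY, with 0.820% at the H3K4me3 map against 17.6% of the 2434. Of the 122, 22 (18%) overlapped a recurring YAP1 region and 15 (12.3%) a recurring BPTF region of induced cells. The YAP1 libraries were uneven here. Of the 100 strongest peaks of induced YAP1 replicates 1 and 4, 49% and 52% lay at recurring GATA3 regions of induced cells. Only 17% and 26% lay at recurring YAP1 regions of the same cells. In replicates 2 and 3, 7% and 12% lay at the GATA3 regions. The cause was not tested, so the overlap does not show shared binding. The strongest gained regions were on chromosome 5 from 53624957 to 53626652 (median rank 3.5), chromosome 6 from 78001934 to 78004086, chromosome 9 from 90885639 to 90887123, chromosome 8 from 128821504 to 128824008, in band 8q24 where MYC lies, and chromosome 13 from 60350254 to 60352409. No gene was assigned to any of them.

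Of the few BPTF regions only in induced libraries, most lay where GATA3 recurred in the same cells, a share that depended on induced replicate 3. Of the 12 regions, 75.0% overlapped a recurring GATA3 region of induced cells and 8.33% the H3K4me3 map. The strongest outside the pericentromere of chromosome 11 were on chromosome 6 from 16769146 to 16770670, chromosome 7 from 134463584 to 134464965 and chromosome 6 from 140322826 to 140324706. All 12 need a peak in replicate 3, of whose 100 strongest peaks 74.0% lay at recurring GATA3 regions of induced cells, against 7% to 24% in the other induced BPTF libraries. Without it, 49 regions were only in induced libraries and 36.7% of them lay at these GATA3 regions, against 0.102% for shifted regions; without replicate 1, 2 or 4 the share was 56.5%, 57.1% and 65.1% of 23, 21 and 63 regions. Without induced replicates 3 and 4, 478 regions were only in induced and 1052 only in control libraries. Across all top peaks, BPTF overlapped recurring GATA3 regions of the same cells in 2.05% ± 0.82 of cases after induction and 10.9% ± 4.6 in control (n = 4 each). On the log2 scale over shifted peaks this was 3.28 ± 0.72 and 4.17 ± 0.57, a difference of -0.89 that did not pass the threshold (exact two-sided permutation p 0.0857). With recurring YAP1 regions the difference was -0.13 (exact two-sided permutation p 0.771).

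YAP1 gave few regions. There were 246 recurring YAP1 regions in control and 254 in induced cells, with 6 shared. Of 58 regions in all control and no induced libraries, 51 lay on chromosome 2 between 16 and 17 Mb, in band 2p24 where MYCN lies, and 9 regions went the other way. The real total of 67 was above the highest other split, 4, and above the 1 to 7 of simulated lists in which each region's libraries were shuffled. Simulated lists with each library drawn anew at each region's share, and no group effect, gave 62, with up to 87 in other splits, where the real lists gave at most 4. Without the interval from 15 to 17 Mb of chromosome 2, 7 regions were only in control and 9 only in induced libraries, so the direction turned. It turned as well without induced replicate 2 (58 only in control, 142 only in induced) or replicate 3 (58 and 92) or both (58 and 2255), and with all deposited peaks (1051 and 2004) or a difference of at least 0.75 in the share of libraries (225 and 236). The 2255 regions need only induced replicates 1 and 4, a looser rule. Of the 100 strongest peaks of these libraries, 49% and 52% lay at recurring GATA3 regions of induced cells, so the 2255 do not show gained YAP1 binding. Peaks with q of at most 0.01 gave 7 and 0. With any of the 4 control libraries left out, another split separated more regions than the real one (94 against 137 without replicate 1, 122 against 134 without replicate 2, 113 against 133 without replicate 3 and 112 against 135 without replicate 4). The strongest gained YAP1 region was on chromosome 12 from 79097511 to 79098587 (median rank 411).

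The same band held the control regions of the other antibodies with the best rank, which follows p and not fold enrichment. The strongest BPTF region of control cells absent after induction was on chromosome 2 from 16078996 to 16082583 (median rank 1.5), and for GATA3 it was on chromosome 2 from 16121662 to 16125422 (median rank 1). The strongest ones elsewhere were on chromosome 19 from 48017466 to 48019284 for BPTF (median rank 6) and on chromosome 9 from 17062363 to 17065865 for GATA3 (median rank 4.5). The authors' fold enrichment on chromosome 2 was only 1.67 to 1.95 for BPTF and 2.74 to 6.99 for GATA3. Elsewhere it was 8.15 to 27.4 and 14.02 to 84.3, so the ranks do not show that binding was strongest on chromosome 2. The band also lies in a stretch where peak density was lower in induced libraries of every antibody, described next. Whether copy number gave these ranks was not tested.

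Peak density differed between control and induced KP-N-YN libraries over long stretches of chromosomes 1, 2 and 10, in all 3 antibodies alike. Induced libraries were lower by a log2 difference of -2.18 over the first 85 Mb of chromosome 1, of -1.73 from 0 to 32 Mb and -1.62 from 37 to 90 Mb of chromosome 2, and of -2.31 from 101 to 136 Mb of chromosome 10. They were higher by 2.34 over the first 39 Mb of chromosome 10. There the control libraries were low, at -2.27 on average, and the induced libraries lay near their own median window, at 0.08. On the chromosome 1 stretch the 12 induced libraries lay between -3.09 and -1.34 and the 12 control libraries between -0.11 and 0.44. Of 201 windows lower by more than 1 in every antibody, all lay on chromosomes 1, 2 and 10, as did 39 of 40 windows that were higher. These steps moved with the condition, so they stand beside every comparison of induced and control cells. With chromosomes 1, 2 and 10 left out, 684 BPTF regions were only in control and 11 only in induced libraries, GATA3 had 1774 and 102, and YAP1 3 and 9. On the 535 shared regions outside these chromosomes, BPTF was at 77.1% ± 17.1 in control and 22.7% ± 18.9 in induced libraries (n = 4 each, exact two-sided permutation p 0.0286).

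**Figure D5:**
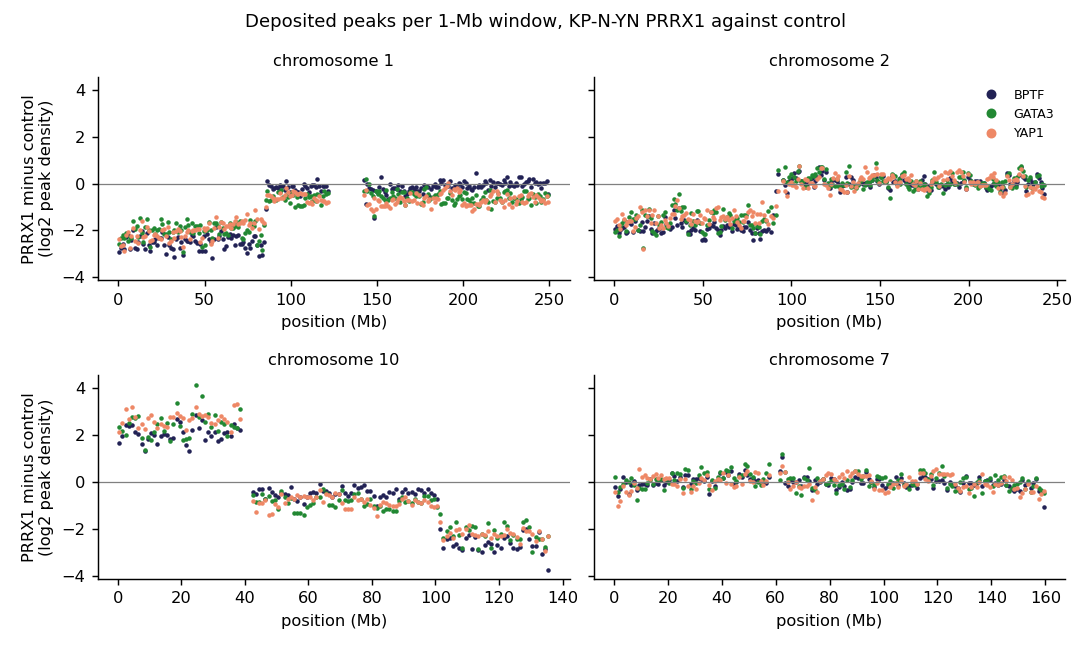
Difference in log2 peak density between PRRX1-induced and control KP-N-YN libraries in 1-Mb windows along chromosomes 1, 2, 10 and 7, with a point per window and antibody (mean of 4 libraries minus mean of 4). Steps of about the same size appear in BPTF, GATA3 and YAP1 at the same positions on chromosomes 1, 2 and 10 (-2.18 over the first 85 Mb of chromosome 1), and chromosome 7 is flat.

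On average, pairs of KP-N-YN libraries of the same condition were more alike than pairs of different conditions, which for BPTF held for the control libraries alone. The mean Jaccard index within and between conditions was 0.0647 and 0.0121 for BPTF, 0.118 and 0.0190 for GATA3, and 0.0143 and 0.00266 for YAP1 (exact one-sided permutation p 0.0286 each). For BPTF the similarity was 0.120 among control libraries and 0.00956 among induced libraries, which is below the value between conditions. Without control replicate 1, 2, 3 or 4 the BPTF difference of 0.0526 fell to 0.0243, 0.0440, 0.0252 and 0.0433 and no longer passed 0.05 (p 0.0857 to 0.114).

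List lengths were compared as well. KELLY lists held 205828 more peaks on average than SK-N-AS lists (exact two-sided permutation p 0.0179, adjusted over 6 tests 0.107), while with q of at most 0.01 they held fewer, by -9225 peaks. The other 5 comparisons of list length gave exact permutation p values of 0.0571 to 1.00.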

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

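The counts over other splits of the libraries and the difference in the number of peaks with q of at most 0.01 were planned; every other test in this part, and the use of that difference to weigh an explanation, was chosen after the result it weighs was seen. Single libraries that lay far from the rest of their group were searched for in 6 measures over 8 groups of 4 or 5 libraries. Chance flags about 1 in 20 groups, so about 2.4 of the 48 searches, and 8 found such a library. In KELLY, BPTF replicate 5 had 357679 deposited peaks against 511196 to 518119 in the others. LAN-1 replicate 3 differed in 3 measures, with 536349 deposited peaks against 243613 to 268798, a log2 overlap with the KELLY H3K4me3 map of 2.63 against 3.94 to 4.07, and 344 top peaks on chromosome 2 from 15 to 17 Mb against 33 to 52. In that interval KP-N-YN control BPTF replicate 4 had 105 top peaks against 18 to 23, and induced GATA3 replicate 4 had 159 against 0 to 6. Replicate 1 of the induced cells had 34370 peaks with q of at most 0.01 for GATA3, against 43 to 1981, and 8090 for YAP1, against 12 to 709.

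The change in overlap with KELLY marks from control to induced libraries differed between antibodies in 3 tests of the difference itself. The change in H3K4me3 overlap was lower for BPTF than for YAP1 by -1.66 on the log2 scale (permutation p 0.0245, adjusted over 6 tests 0.0490). The change in H3K27me3 overlap was higher for BPTF than for YAP1 by 0.92 (permutation p 0.00122, adjusted 0.00735) and for GATA3 than for YAP1 by 1.26 (permutation p 0.00531, adjusted 0.0159). These tests do not separate an effect of induction from the strength of the libraries: YAP1 started from an H3K4me3 overlap of 1.80 in control libraries, against 4.08 for BPTF, and control YAP1 libraries had 91.5 peaks with q of at most 0.01 on average. BPTF libraries also had more antibody, 10 µg against 1 µg for GATA3 and YAP1.

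The first pattern weighed is the peak density of LAN-1 replicate 4. A KELLY library under a LAN-1 label is a candidate explanation, since its profile correlated with the KELLY libraries at a mean r of 0.41, each above its r with any other LAN-1 library. Spread between LAN-1 replicates is argued against by its highest r with replicates 1 to 3, -0.62, where these reached at least 0.74 with each other. A swap between both groups is argued against as well, because no KELLY library resembled LAN-1: the highest r of any with LAN-1 replicates 1 to 3 was 0.0072, far below 0.74. On the log2 density itself, without the shared mean that lowers r between groups, it was 0.60, still below the lowest r among LAN-1 replicates 1 to 3 of 0.90, where replicate 4 reached at most 0.21. The KELLY group is itself uneven, with r between its libraries from -0.011 to 0.89. Of its top peaks from 15 to 17 Mb of chromosome 2, 3.85% lay in the lower part of that interval. KELLY libraries had 0.203% to 4.69% there, and LAN-1 replicates 1 to 3 had 37.5% to 66.7%. This goes with a KELLY library, unless the control library behind the list had extra copies in that part. Another control library in its peak calling is therefore less favoured by these values but not excluded. The list also correlated with the KELLY H3K4me3 list (r = 0.49), and the control libraries are not given in the sources used here. No biological explanation was tested.

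The second pattern is the set of steps in density on chromosomes 1, 2 and 10 between induced and control KP-N-YN libraries. Changed binding of a single antibody's target is argued against, because without the 50000 strongest peaks of each library the lowest correlation between antibodies across windows was still 0.82. A few libraries as the source are argued against by the highest of the 12 induced libraries on the chromosome 1 stretch, -1.34, which lay below the lowest control library, -0.11. Cells of the conditions that differ in copy number (-2.18 on the chromosome 1 stretch) and peak calling against control libraries that differ in copy number (2.34 on the first stretch of chromosome 10) predict the same steps and cannot be told apart from peak lists. An effect of PRRX1 on these stretches stays open and untested.

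The third pattern is the lower number of recurring BPTF regions after induction. The steps in density as its whole cause are argued against by the 684 regions found in every control and no induced library outside chromosomes 1, 2 and 10, above the 113 of the highest other split there. A single deviating library is argued against by the regions shared by the other lines, of which the highest induced library held 40.9% and the lowest control library 59.4%. Lower enrichment in the induced BPTF libraries stays open, since they had fewer peaks with q of at most 0.01 (a difference of -4195), which lost binding gives as well. A biological loss of BPTF after PRRX1 induction is therefore a hypothesis beside it.

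Chance as the source of the separated regions was examined with the other splits of the same libraries. With the top peaks of all libraries, in 5 comparisons only the real split, 1 of 35 or 1 of 56, gave as many regions. That is the smallest share these splits allow, and it argues against chance in that setting. The comparisons were KELLY against SK-N-AS (1728, highest other 257), LAN-1 against SK-N-AS (2051 and 584), and PRRX1 against control for BPTF (1001 and 134), GATA3 (2556 and 173) and YAP1 (67 and 4). Some alternatives brought the share to 0.05 or more for all but GATA3. With all deposited peaks, 5 of 56 splits gave at least the real 6332 for KELLY against SK-N-AS (highest 15146), and 2 of 35 the real 7619 for LAN-1 against SK-N-AS (highest 8839). For KP-N-YN BPTF, 3 of 35 splits did so without induced replicate 1 (1118, highest 1237), 2 (1182 and 1299) or 3 (1056 and 1181), and 2 of 35 without replicate 4 (1095 and 1203). For YAP1 it was 2 of 35 without control replicate 1 (94 and 137), 2 (122 and 134), 3 (113 and 133) or 4 (112 and 135). With 3 libraries left in a condition, another split can set 3 libraries of the full condition against all the rest. That rule is easier to meet: 4809 control BPTF regions were in at least 3 libraries and 1551 in all 4. Such a split still holds the condition difference, so these KP-N-YN totals do not decide about chance. For KELLY against LAN-1, 4 of 100 splits gave at least the real 82 and the highest gave 158. That share is under 0.05 in this setting but not in 8 of 15 alternatives, such as peaks with q of at most 0.01 (5 of 100 splits). Chance therefore stays open for this comparison. A split that separates more regions than the real one points to a structure of the samples, and the highest one placed LAN-1 replicate 4 with KELLY libraries.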

How the results depend on the processing

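Among 217 results under alternatives, 152 kept their direction and their side of the threshold or stayed within 1.5 times the main count or 1 SD of the main value, 7 lost and 1 gained the threshold, 42 moved and 15 reversed. Counts of separated regions were judged here by size and direction alone. Of their 94 alternatives, 18 brought the share of splits with as many regions to 0.05 or more (none of them for GATA3), and 14 left too few splits for a lower share. Leaving out intervals, chromosomes or pairs of libraries, and mark peaks at q of at most 0.01, were chosen after the data were seen. Where no cause is named below, the cause was not tested. Using summits changed no separated count by construction.

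Separated regions mostly grew with list length. The top 50000 peaks gave 156 for KELLY against LAN-1, 1949 for KP-N-YN BPTF and 155 for YAP1. All deposited peaks gave 6332 and 7619 for KELLY and LAN-1 against SK-N-AS, 2339 for KELLY against LAN-1, 5929 for BPTF, 7015 for GATA3, and 3055 with the direction reversed for YAP1. Peaks with q of at most 0.01, in lists of 6 to 34370, gave 1701 and 2327 for KELLY and LAN-1 against SK-N-AS (main 1728 and 2051), 44 for KELLY against LAN-1, 156 for BPTF, 811 for GATA3 and 7 for YAP1. A difference of at least 0.75 in the share of libraries, a looser rule, gave 2851, 3612, 737, 4035, 7820 and, reversed, 461 in the order of the comparisons. Without the chromosome 2 interval YAP1 fell to 16, reversed, and without chromosomes 1, 2 and 10 to 12, reversed.

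Leaving out a library loosens the rule by construction. Counts then ran from 1906 to 3522 for KELLY against SK-N-AS (3522 without SK-N-AS replicate 1, 2602 without replicate 2), 2214 to 4063 for LAN-1 against SK-N-AS (4063 without SK-N-AS replicate 1), and 103 to 315 for KELLY against LAN-1. There they were 315 without LAN-1 replicate 4, 160 and reversed without replicate 3, 128 and 125 without replicates 1 and 2, and 160, 171 and 128 without KELLY replicates 2, 4 and 5. Only without KELLY replicate 2 (136 in the highest other split) or LAN-1 replicate 4 (268) did no other split give as many regions there. The other libraries left out did not give this, so chance stays open for KELLY against LAN-1. Counts ran from 1056 to 2166 for KP-N-YN BPTF (2166 and 2069 without control replicates 2 and 4). With an induced library left out, 1 or 2 other splits gave more there (up to 1299). Counts were 2637 to 4198 for GATA3 (4198 without control replicate 3, 4074 without induced replicate 3), and 71 to 200 for YAP1. YAP1 reversed at 200 without induced replicate 2 and at 150 without replicate 3, and gave 122, 113 and 112 without control replicates 2, 3 and 4. Without any of the control replicates, 1 to 4, another split gave more, up to 137. Pairs left out gave 12032 and 12832 for KELLY and LAN-1 against SK-N-AS without SK-N-AS replicates 1 and 3 (an excess the single library left fixes by construction), 1530 for BPTF without induced replicates 3 and 4, and 2313, reversed, for YAP1 without induced replicates 2 and 3.

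The log2 overlap of BPTF with H3K4me3 in KELLY was 2.33 with the top 50000 peaks, 1.28 with all peaks, 3.44 with q of at most 0.01, 3.60 with summits and 4.04 with the stricter mark peaks, and 2.75 to 2.89 with a library left out. For H3K27me3 it was 0.19 with the top 50000 peaks, 0.32 with all peaks, -0.33 and reversed with q of at most 0.01, and 0.07 to 0.13 with a library left out. Their difference, whose sign map width fixed, stayed at 2.63 to 2.81 with a library left out. The BPTF and GATA3 overlap difference ran from -1.10 to -0.54 with a library left out, and was -0.52 with q of at most 0.01. That with YAP1 ran from -0.39 to 0.12 with a library left out, reversed to 0.12 without induced or control BPTF replicate 4 and to 0.28 without the chromosome 2 interval, and was -0.49 with all peaks and -0.94 with q of at most 0.01.

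The similarity difference between lines was 0.0148 to 0.0468 with a library left out, and passed no threshold without SK-N-AS replicate 1 (0.0168), 2 (0.0167) or 3 (0.0148). In KP-N-YN it was 0.0243 to 0.0739 for BPTF, past the threshold except without control replicates 1, 2, 3 or 4 (0.0243, 0.0440, 0.0252 and 0.0433), 0.0698 to 0.131 for GATA3 and 0.00804 to 0.0146 for YAP1. With q of at most 0.01, the list length difference reversed to -9225 and -11057 for KELLY and LAN-1 against SK-N-AS and to -1393 for GATA3, and passed the threshold for BPTF at -4195. Treating replicate numbers as a block gave p 0.125 for each KP-N-YN separated count (1001, 2556 and 67), the smallest that 4 pairs allow. The planned gene lists, locus scores, flank and promoter windows, and motif searches were not run.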

Other observations

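Every test in this part was chosen after the data were seen. Recurring BPTF regions that stayed after induction were few but not random: of the 229 in induced cells 33.2% overlapped a control region, against 0.742% for shifted regions. For GATA3 11.3% of 2493 did so, against 0.844%. YAP1 top peaks overlapped recurring GATA3 regions of the same cells by a log2 ratio of 3.11 ± 1.61 after induction and 1.98 ± 0.75 in control (n = 4 each, exact two-sided permutation p 0.314, adjusted over 18 tests 0.333).

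In SK-N-AS, which carries no MYCN amplification, replicates 1 and 3 had 430 and 319 top peaks on chromosome 2 from 15 to 17 Mb, and replicate 2 had 3. Carry-over from an amplified line is a candidate explanation that was not tested. Without the interval the regions separating KELLY and SK-N-AS were 1727. The few peaks of replicate 2 nearly fix this value in advance, and it does not exclude carry-over elsewhere in the genome. The strongest peaks of SK-N-AS replicate 1 were on chromosome 6 from 74229765 to 74231557 and chromosome 14 from 20809943 to 20812134, with an authors' fold enrichment of 349 and 276. Of the 100 strongest peaks of induced BPTF replicate 3, 74.0% lay at recurring GATA3 regions of induced cells, and it held a peak at 1.65% of the 667 regions shared by the other lines. Induced GATA3 replicate 3 had 31.0% of its 100 strongest peaks there, against 97.0% to 100% in the other induced GATA3 libraries. A wrong label of the BPTF library is a candidate explanation for part of the overlap between induced BPTF and GATA3 regions; without it (1056 separated regions) 18 of 49 regions only in induced libraries still lay at GATA3 regions. Across the regions of each antibody, departures from the group's mean presence correlated between control and induced libraries of the same replicate number at -0.0087 to 0.0552.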
